A study of Mus musculus with 2 samples.

How the data were processed

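The series holds RNA-seq of liver from male C57BL/6 mice on a high-fat diet, with 1 library from RORα f/f control liver and 1 from RORα f/f:Alb-Cre liver, labelled LKO. Per the labels' protocols, RNA was extracted with Trizol and 500 ng of total RNA entered a LEXOGEN mRNA-Seq kit. Whether a library held RNA of 1 animal or of several is not given in the sources used here.

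The authors deposited whole-number read counts per gene symbol, 1 table per library, with no normalization. Per the submitters' processing notes, TopHat and edgeR were used with build mm10, without versions or roles. The counter, the gene annotation, the read layout, the use of strand and the treatment of reads with several alignments are not given in the sources used here. The values bear on this in 3 ways. Among genes with 1 to 49 counts, even counts made up 54.3% in the control library and 50.7% in the library labelled LKO where RefSeq lists 1 curated transcript. They made up 67.9% and 67.1% where it lists 2, as when a count is a sum over transcripts. Further, 76 groups holding 160 genes had equal counts of at least 50 in both libraries, as when reads are counted at each copy. Lastly, neighbouring genes at some loci shared their count differences. Intervals are therefore too narrow where a read was counted more than once, and genes with close copies (Mup, Cyp4a, Cyp2b, Ces1, Hsd3b, histone and globin genes) have uncertain splits. As strand use is unknown, reads of overlapping and antisense genes cannot be told apart.

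Total counts were 128201591 in the control library, with 16705 of 24421 genes above 0, and 131843686 in the library labelled LKO, with 17145. The median sum of both counts over measured genes was 2489. TMM factors from edgeR 4.0.16 in R 4.3.3 were 0.865 and 1.16. CPM are counts scaled to the total count times this factor. For each gene the ratio of CPM, library labelled LKO over control, was computed with a 95% Clopper-Pearson interval conditional on the sum of both counts. PCR duplicates without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A count of 0 was set to a floor of 3 counts for a fold, 0.0271 CPM in the control library and 0.0197 CPM in the library labelled LKO. Such folds are rough bounds, and the interval limit can lie below them. No test and no p-value was computed, as 1 library per group leaves no spread between replicates.

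A gene was measured with a mean CPM of at least 1 and a summed count of at least 20, and it counted as higher or lower at 2-fold with an interval that excluded 1. Gene lists and cell type markers were fixed before the data were examined, 42 in all, of which 35 had at least 5 measured members. For each list the members at least 1.5-fold higher or lower with an interval that excluded 1 were counted. The median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Of the 35 medians, 18 lay outside the central 95% of their random lists, 11 above and 7 below. Members of 1 list can be regulated together, so these percentiles are not error rates.

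Genes were named by a rule fixed before the data were examined. It took Rora, the 10 largest and 10 smallest ratios among 2-fold genes with a mean CPM of at least 5, and the 5 most abundant genes of each library. It also took up to 3 highest, 3 lowest and 2 most abundant measured members of each list. Unnamed gene models, small RNAs, pseudogenes, ribosomal RNA and Mup genes were left out of the ranking by ratio. Pparg, Cd36, Fasn, Srebf1, Acadm, Cyp3a11, Cyp4a12b and Hspa5 fall outside the rule and were chosen from their lists after their values were seen. A few genes that the rule names are not reported here.

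Symbols were matched to GENCODE M21 (GRCm38, the assembly of mm10) and to RefSeq, where 24299 of 24421 symbols matched. Coordinates are from GENCODE. Transcript length and GC content, from the longest transcript, were found for 11059 measured genes (99.3%). Their trend was removed with lowess smoothing (fraction 0.3) fitted without ribosomal protein and respiratory chain genes.

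The procedure was tested on simulated counts for the 11137 measured genes of this comparison, drawn as independent Poisson counts. They held no reads counted more than once and no spread between animals. The rates of calls and of interval coverage thus check the procedure, not the error in these data. It called 50 of 50 genes simulated at 3-fold higher, 49 of 50 at 3-fold lower, 0 of 50 at 1.5-fold higher and 0 of 10912 unchanged genes. Intervals held the true ratio for 95.1% of 11109 simulated genes, and 8 of 100 random lists of the real ratios lay outside the central 95%. Alternatives were other scalings (total count, median of ratios from DESeq2 1.42.0, upper quartile, totals without the 20 most abundant genes), added counts of 0.5 and 5, other filters, fold thresholds of 1.5 and 3, other interval criteria, unmatched random lists and list means. Further alternatives were chosen after the data were seen, among them counts divided by the number of RefSeq transcripts, which entered the intervals only. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.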

Results

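Liver RNA was sequenced from male C57BL/6 mice given a high-fat diet for 12 weeks from 6 weeks of age. 1 library came from control liver with floxed Rora alleles (RORα f/f). 1 library was labelled as a liver-specific knockout (LKO), in which Cre under the albumin promoter was to remove the floxed part of Rora in hepatocytes. By its title, the series asked which genes depend on RORα, a nuclear receptor, as non-alcoholic steatohepatitis progresses. Read counts for 24421 genes summed to 128201591 in the control library and 131843686 in the library labelled LKO. Of these genes, 11137 were measured, with a mean of at least 1 CPM (counts scaled to library size) and a summed count of at least 20. With 1 library per genotype, no difference has a replicate check. Every ratio compares these 2 libraries, and each interval is a 95% exact interval that covers counting error only. For 95% of genes with a mean CPM of 10 or more, the interval reached no further than 1.08 times either side of the ratio.

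The control library was dominated by a few liver secretory genes. The 20 annotated Mup genes, which encode major urinary proteins, held 23.0% of all counts in the control library and 9.08% in the library labelled LKO. Alb held 10.2% and 10.5%. The 5 most abundant genes of the control library were Alb, Mup2, Gm2083, Mup10 and Serpina1a. Alb, Mup2, Gm2083 and Serpina1a were also among the 5 most abundant in the library labelled LKO. Because of this shift, levels are given as CPM scaled by the trimmed mean of M-values (TMM), and each ratio is relative to the bulk of genes. Scaling by total count instead would raise every log2 ratio by 0.42, so that a ratio from −0.42 to 0 would turn positive. Totals without the 20 most abundant genes would raise it by 0.12.

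Rora itself was nearly equal in raw counts, with 3701 in the control library and 3677 in the library labelled LKO. After scaling this was 33.4 and 24.1 CPM, or 1.38-fold (interval 1.32 to 1.45) lower, and the log2 ratio was −0.47. With total-count scaling the log2 ratio was −0.05, and without the 20 most abundant genes in the totals it was −0.35. Rora lies on chromosome 9 from 68653786 to 69388246 on the plus strand (mm10) and is annotated as protein coding. The value is a total over the gene, so exons outside the deleted part add to it and it checks the genotype label only in part. As the total of the targeted gene was not lost, all directions are stated for the library labelled LKO, not for loss of RORα.

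Between the 2 libraries, 426 genes were at least 2-fold higher in the library labelled LKO and 292 were at least 2-fold lower, each with an interval that excluded a ratio of 1. With total-count scaling the split was 1182 against 123. Most measured genes, 8881 or 79.7%, lay within 1.5-fold. Cyp2b9, a female-biased cytochrome P450, had the largest ratio among the genes named by rank, at 172-fold (interval 141 to 213) higher. Rgs16, a regulator of G protein signalling, was 75.5-fold (interval 64.2 to 89.3) higher. On the other side, the steroid dehydrogenase genes Hsd3b5 and Hsd3b4 were 471-fold (interval 285 to 842) and 660.3-fold (interval 257 to 2426) lower, the latter with 1920 counts against 4. Serpina3j was 212-fold lower and Tff3, a trefoil peptide gene, 89.4-fold lower. Of the 20 genes ranked by ratio, 11 had a neighbour within 250 kb whose count difference was within 5% of theirs or a whole multiple. These 11 are among the genes named next, of which only Duxbl1 and Hist1h4n had no such neighbour. Hist1h4d, Hist1h3d, Hist1h2ad and Hist1h1e were 29.8-fold to 115-fold higher, and Duxbl1, Duxbl2 and Duxbl3 were 60.1-fold to 60.9-fold higher. Hist1h2ao, Hist1h2ap and Hist1h4n were 9.88-fold to 24.4-fold lower. Prss16, Zfp184 and Pom121l2 had 8964, 4482 and 2241 counts in the control library and 0 in the library labelled LKO. Against a floor of 3 counts they were 4110-fold, 2055-fold and 1028-fold lower, with lower interval limits of 3342, 1671 and 835. These control counts are whole multiples of one another, so reads may have been counted more than once and the folds and limits may be too high.

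Genes for lipid uptake, storage and droplets were higher in the library labelled LKO. Of 23 measured members of the PPARγ and lipid droplet list, 19 were at least 1.5-fold higher and 0 were at least 1.5-fold lower. Cidec, which enlarges lipid droplets, was 14.3-fold (interval 13.2 to 15.5) higher, at 5.65 and 80.7 CPM. The lipoprotein receptor gene Vldlr and the monoacylglycerol acyltransferase gene Mogat1 were 14.9-fold (interval 10.4 to 21.9) and 14.8-fold (interval 10.2 to 22.2) higher. From 32 and 29 counts in the control library, both passed the filter only through the library labelled LKO, which tilts this split. Lpin1, a phosphatidate phosphatase gene of triglyceride synthesis, stood at 152 and 784 CPM, 5.17-fold (interval 5.09 to 5.26) higher. Pparg and the fatty acid uptake gene Cd36 were 2.79-fold and 4.45-fold higher. Lpl and Fabp4 differed little, with log2 ratios of −0.17 and 0.06, the first of which turns positive with total-count scaling. The list median was a log2 ratio of 1.06. All 10000 random lists matched on expression lay below it, and their central 95% ran from −0.21 to 0.21.

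Fatty acid synthesis genes followed the same direction, with 15 of 26 measured members at least 1.5-fold higher and 1 lower. Scd1, which introduces the first double bond into saturated fatty acids, stood at 3397 and 10198 CPM, 3.0-fold (interval 2.99 to 3.01) higher. Acacb, an acetyl-CoA carboxylase gene, was 3.70-fold higher, the elongase gene Elovl5 3.01-fold and the desaturase gene Scd2 3.09-fold. Fasn, the fatty acid synthase gene, was 2.55-fold higher. The exception was Elovl3, an elongase gene with male-biased expression, at 2.97-fold (interval 2.89 to 3.05) lower. The transcription factor genes Srebf1 and Nr1h3 had log2 ratios of −0.33 and −0.36, both positive with total-count scaling. The list median of 0.69 lay above all 10000 random lists.

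Cholesterol synthesis genes were higher by a smaller amount. Of 24 members, 5 were at least 1.5-fold higher and 0 lower, and the median log2 ratio was 0.41, above all 10000 random lists. Hmgcs1, at the entry of the pathway, was 2.47-fold (interval 2.39 to 2.54) higher. Dhcr7, which acts at its end, was 1.73-fold higher. Insig1 had a log2 ratio of −0.20, which turns positive with total-count scaling.

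Fatty acid oxidation genes and targets of PPARα were also higher in the library labelled LKO. Of 28 measured members, 19 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 1.11, above all 10000 random lists (central 95% −0.21 to 0.17). The largest ratios of the list included microsomal omega-hydroxylase genes. Cyp4a31 was 44.0-fold (interval 42.9 to 45.1) higher, Cyp4a32 23.1-fold, Cyp4a10 5.69-fold and Cyp4a14 5.25-fold. Cyp4a12a and Cyp4a12b, male-biased genes of the same family outside this list, were 1.75-fold and 3.76-fold lower. These genes are close copies of one another, so reads can be split between them. Cpt1a, which admits fatty acids to mitochondria, was 2.07-fold higher. Fgf21, which encodes a fasting-induced hormone, was 4.59-fold higher. Among mitochondrial β-oxidation genes, Hadhb and Acadm had log2 ratios of 0.01 and 0.23. Fabp1 had a log2 ratio of −0.43, which was −0.01 with total-count scaling and 0.03 after removal of a trend with transcript length and GC content.

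**Figure D1:**
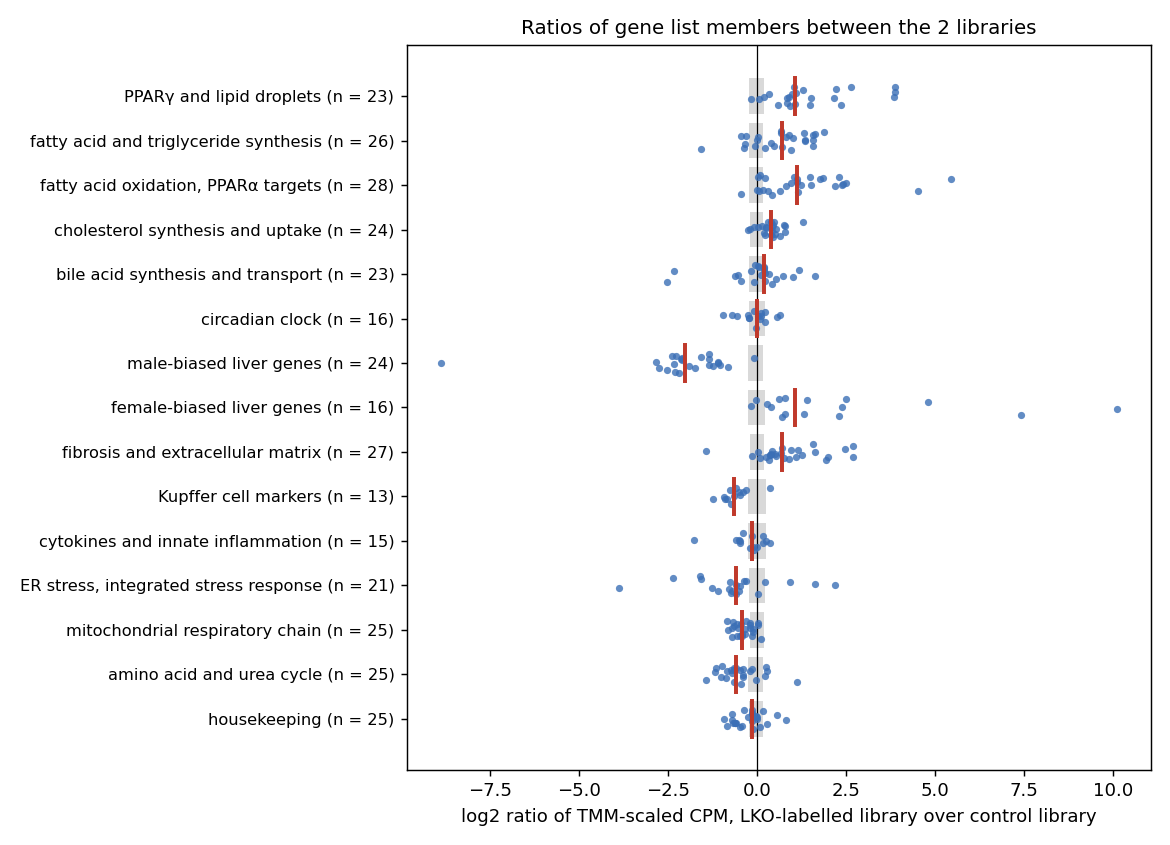
Each point is the log2 ratio of 1 measured gene, library labelled LKO over control library, in 15 gene lists. Red lines mark list medians and grey bars the central 95% of medians of 10000 random lists matched on expression. The medians run from −2.01 for male-biased liver genes to 1.11 for fatty acid oxidation and PPARα targets. With total-count scaling every point, red line and grey bar would move right by 0.42. The housekeeping and cytokine medians would then be positive but keep their place against the bars.

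Glucose genes went both ways. In the list of gluconeogenesis, glycogen and insulin signalling, 7 of 19 measured members were at least 1.5-fold higher and 4 lower. The glucose-6-phosphatase gene G6pc was 2.53-fold (interval 2.49 to 2.57) lower. Sds and Tat, which break down serine and tyrosine, were 2.69-fold and 2.24-fold lower, and Pck1, the cytosolic gluconeogenic carboxykinase gene, was 1.42-fold lower. In contrast, the pyruvate carboxylase gene Pcx was 2.01-fold higher and Irs2, an insulin receptor substrate gene, 1.68-fold higher. The median of 0.06 and the mean of −0.03 differed in sign, and 74.6% of random lists lay below the median. Without members that other lists hold, the median was 0.49, above 99.98% of random lists.

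Bile acid genes also went both ways, with 4 of 23 members at least 1.5-fold higher and 3 lower. Cyp7b1, of the alternative pathway of bile acid synthesis, was 5.71-fold (interval 5.56 to 5.87) lower. Cyp7a1, the rate-limiting enzyme of the classical pathway, was 1.52-fold lower, while Cyp8b1, which sets cholic acid synthesis, was 2.03-fold higher. Among transporters, Slco1a1 was 4.99-fold lower and Abcc3, a basolateral exporter gene, 3.12-fold higher. The list median was 0.19, at percentile 97.1 of random lists and inside their central 95%, and at percentile 98.9 once a trend with transcript length and GC content was removed. Among 20 apolipoprotein and lipoprotein export genes, 3 were at least 1.5-fold higher and 2 lower, with a median of −0.03, a mean of 0.22 and a percentile of 57.4. Apoa4 was 2.78-fold higher, Apom 1.85-fold lower and Apoe, with a log2 ratio of 0.01, nearly equal. The carboxylesterase genes Ces1d and Ces1g in that list were 4.44-fold and 8.91-fold higher.

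Of 17 measured genes named as RORα targets in earlier work, 5 were at least 1.5-fold higher and 6 lower. Hsd3b5, Cyp7b1, Elovl3 and G6pc were lower, and Fgf21, Cpt1a and Cyp8b1 higher, by the folds given above. The median log2 ratio was −0.36, at percentile 0.60 of random lists, and with total-count scaling it was 0.05. Other lists hold 14 of the 17 genes. The circadian clock list had a median of 0.02 and a percentile of 58.1, with 1 of 16 members at least 1.5-fold higher and 2 lower. Arntl, the clock activator known as Bmal1, was 1.95-fold (interval 1.83 to 2.08) lower and Cry1 1.62-fold lower. Nr1d1, a repressor of Arntl, was 1.57-fold higher.

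Male-biased liver genes were lower, and female-biased liver genes higher, in the library labelled LKO. Of 24 male-biased genes, 23 were at least 1.5-fold lower in the library labelled LKO and 0 higher. Besides Hsd3b5 and Elovl3, the protease inhibitor gene Serpina1e was 7.11-fold (interval 7.09 to 7.14) lower and Mup20, which encodes the pheromone darcin, 6.68-fold lower. Mup1 was 4.94-fold lower, a value that can share reads with other Mup copies. Cyp2d9 had a log2 ratio of only −0.07, which turns positive with total-count scaling. Of 24 female-biased genes 16 were measured, and of these 12 were at least 1.5-fold higher and 0 lower. Genes near 0 in the control library, such as Cyp2b13 and Hao2, passed the filter only through the library labelled LKO, which tilts this split. Other lists hold 7 of the 16, among them Cyp4a10 and Cyp4a14. Cyp2b13 had 1 count in the control library and 1517 in the library labelled LKO, a ratio of 1103 (interval 198 to 43587). Hao2, a hydroxyacid oxidase gene, was 27.8-fold higher. The medians were −2.01, below all 10000 random lists, and 1.06, above all of them.

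Xenobiotic metabolism genes were higher as a list in the library labelled LKO. Other lists hold 7 of the 29 measured genes, among them Cyp2b9 and Cyp2b13 as female-biased genes. Of the 29, 13 were at least 1.5-fold higher and 4 lower, with a median of 0.54, above all 10000 random lists. Cyp2b10, an inducible target of the receptor CAR, was 37.4-fold (interval 21.3 to 72.9) higher from 12 counts in the control library. Cyp3a11, a target of the receptor PXR, was 2.0-fold higher, and Cyp2e1 1.45-fold higher. Cyp2c54 and Gsta2 were 3.39-fold and 2.53-fold lower.

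**Figure D2:**
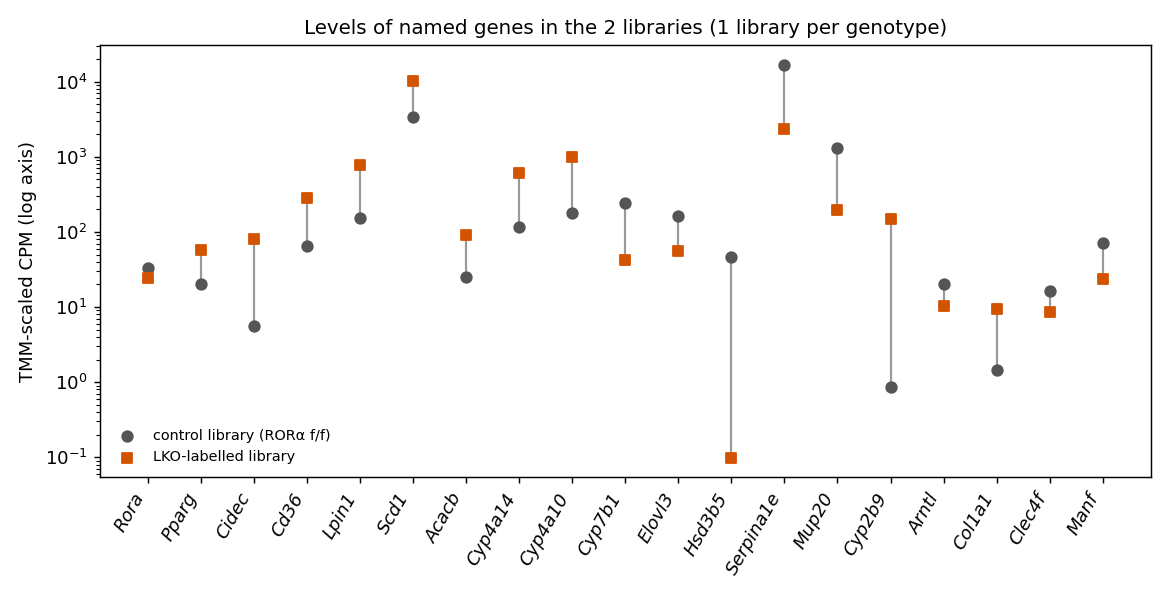
TMM-scaled CPM on a log axis for 19 genes in the control library (circles) and the library labelled LKO (squares), with 1 library per genotype. The widest gaps are Hsd3b5, at 46.3 and 0.0984 CPM, and Cyp2b9, at 0.866 and 149 CPM, while Rora lies at 33.4 and 24.1 CPM.

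Extracellular matrix genes were higher in the library labelled LKO. Of 27 measured members of the fibrosis list, 15 were at least 1.5-fold higher and 1 lower, and the median of 0.71 lay above all 10000 random lists. The collagen genes Col1a1, Col1a2 and Col3a1 were 6.48-fold (interval 5.50 to 7.69), 4.03-fold and 3.09-fold higher. Mmp12, a macrophage elastase gene, was 6.46-fold higher and Timp1, an inhibitor of metalloproteinases, 5.55-fold higher. From 35 and 46 counts in the control library, both passed the filter only through the library labelled LKO, which tilts this split. Col5a2 was 2.70-fold lower. Acta2, the smooth muscle actin gene of activated stellate cells, had a log2 ratio of −0.14, and it turns positive with total-count scaling. Stellate cell and fibroblast markers had a median of 0.46, at percentile 99.95, with 7 of 17 at least 1.5-fold higher and 1 lower, and 5 of these genes stand in other lists. Without those 5 the median was 0.26 and the percentile 96.0, and at a mean CPM of 10 or more it was 0.21 and 89.0, both inside the central 95%.

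Markers of resident liver macrophages were lower, and the measured members of inflammatory gene lists did not stand apart as lists. Of 13 measured Kupffer cell markers, 8 were at least 1.5-fold lower and 0 higher, with a median of −0.64 below all but 1 of 10000 random lists. Clec4f was 1.85-fold (interval 1.73 to 1.99) lower, Timd4 2.34-fold and Cd5l 1.90-fold. Of 16 markers of recruited macrophages and monocytes, 10 were measured, with a median of −0.28 and a percentile of 4.43. Among them Gpnmb, a gene of lipid-loaded macrophages, was 3.96-fold higher and Trem2 had a log2 ratio of −0.12. That median and the log2 ratio of Trem2 both turn positive with total-count scaling. Of 31 cytokine and chemokine genes only 15 were measured, so the others could not be read. Those 15 had a median of −0.14 (percentile 14.9), with 0 higher by 1.5-fold and 2 lower. Interferon genes had a median of −0.11 (percentile 19.3), with 2 of 21 higher and 3 lower. Il1a was 3.37-fold lower and Irf7 2.07-fold lower. Acute phase genes had a median of −0.16 and a mean of 0.11, a percentile of 11, and 5 of 24 members higher and 4 lower. Among them Lcn2, which binds bacterial siderophores, was 5.78-fold (interval 5.11 to 6.55) higher, the interleukin 1 receptor antagonist gene Il1rn 5.58-fold higher and Orm3 4.18-fold lower. The medians of these 3 lists also turn positive with total-count scaling.

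Other cell types gave few differences, though only 6 of 11 dendritic cell, 5 of 13 cholangiocyte and 5 of 11 adipocyte genes were measured. Endothelial markers had a median of 0.12 (percentile 87.5), cholangiocyte markers −0.27 (12.3), dendritic cell and antigen presentation genes −0.18 (17.9), adipocyte markers 0.32 (91.0) and red blood cell genes 0.19 (89.2). The cholangiocyte and dendritic cell medians turn positive with total-count scaling, and the red blood cell median was 0.51, at percentile 99.2, after a length and GC trend was removed. Hba-a1 and Hba-a2 had equal counts, as had Hbb-b2 and Hbb-bt, so red blood cell percentiles treat copies as separate members. In that list 0 of 8 measured genes were at least 1.5-fold higher and 1 lower, Alas2 at 1.94-fold. Neutrophil, T and NK cell, B and plasma cell, mesothelial, pancreas, intestine and stomach, and muscle lists had fewer than 5 measured members and were given no median. General hepatocyte markers had a median of −0.33 and a percentile of 3.52, with 0 of 14 at least 1.5-fold higher and 5 lower. Without a filter the percentile was 2.40 and against unmatched random lists 0.76, both outside the central 95%, while the median was 0.09 with total-count scaling. Periportal markers were lower, with a median of −0.57 below all but 9 random lists and 6 of 12 at least 1.5-fold lower, among them the histidine ammonia-lyase gene Hal at 1.97-fold. Other lists, such as those of amino acid and glucose genes, hold 9 of these 12, so this is not a separate set of genes. Pericentral markers had a median of 0.28 at percentile 97.6, with 3 of 12 higher and 1 lower, and several other settings placed it inside the central 95%. Glul, the glutamine synthetase gene, was 2.2-fold (interval 2.17 to 2.23) higher, Axin2, a Wnt target, 2.13-fold higher and Cyp1a2 1.63-fold lower.

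Amino acid and urea cycle genes, and genes of the endoplasmic reticulum and integrated stress responses, were lower as lists. In the amino acid and urea cycle list, 12 of 25 members were at least 1.5-fold lower and 1 higher, with a median of −0.57 below all 10000 random lists, and other lists hold 10 of the 25. The transsulfuration gene Cth was 2.23-fold lower and Ass1, of the urea cycle, 1.32-fold lower, though higher with total-count scaling. In the stress response list, 12 of 21 members were at least 1.5-fold lower and 3 higher, with a median of −0.59 below all 10000. The asparagine synthetase gene Asns was 14.6-fold (interval 10.1 to 21.9) lower, and Sdf2l1 and Manf, which act in protein folding, 5.15-fold and 3.01-fold lower. Hspa5, which encodes the chaperone BiP, was 2.38-fold lower. In contrast, the 3 higher members were Fgf21 at 4.59-fold, Chac1 at 3.09-fold and Sesn2 at 1.91-fold.

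Respiratory chain genes had a median of −0.42, below all but 3 random lists, with 6 of 25 members at least 1.5-fold lower and 0 higher. Cox6c and Ndufa1, small subunits of complexes IV and I, were 1.80-fold and 1.75-fold lower. Ndufs1 and Uqcrc1 had log2 ratios of 0.04 and 0.02. With total-count scaling the median of this list was about 0. Across genes, which are not independent replicates, the log2 ratio was higher for longer transcripts (Spearman's rho 0.221), from a median of −0.28 in the decile of shortest transcripts to 0.14 in the decile of longest ones.

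Immediate early genes were higher as a list and proliferation genes by their median, while oxidative stress genes differed at few members. Immediate early genes had a median of 0.68, above all 10000 random lists, with 7 of 14 at least 1.5-fold higher and 1 lower, led by Jun at 5.03-fold (interval 4.68 to 5.40) and Egr1 at 4.07-fold. Oxidative stress genes had a median of −0.04, a mean of 0.33 and a percentile of 40.5, and 3 of 20 passed 1.5-fold, all higher. These were the metallothionein genes Mt1 and Mt2, at 7.09-fold and 13.6-fold, and the quinone reductase gene Nqo1, at 2.12-fold. Of 21 proliferation genes, 14 were measured, with a median of 0.51 (percentile 99.93). By the mean of members the percentile was 96.3, inside the central 95%. The 3 at least 1.5-fold higher were Cdkn1a, a cell cycle inhibitor gene, at 3.36-fold, Myc at 2.16-fold and Gadd45a at 1.55-fold. The 2 lower were Ccne2 and Gadd45g, each at 2.07-fold. Corepressor complex genes had a median of 0.25 (percentile 95.5), with 1 of 11 higher, Tbl1xr1 at 2.27-fold, and 1 lower, Tbl1x at 1.70-fold. Of 25 housekeeping genes, 1 was at least 1.5-fold higher and 8 lower, with a median of −0.15 and a percentile of 11.2, and a median of 0.27 with total-count scaling. At a mean CPM of 10 or more the percentile was 1.56, and after removal of the length and GC trend 0.89, both outside the central 95%. Gapdh had a log2 ratio of 0.29, and the ribosomal protein gene Rpl13a was 1.89-fold lower.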

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

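The alternatives that remove a length and GC trend, leave out members of other lists, leave out Mup genes, leave out loci with shared count differences or divide counts by RefSeq transcripts were chosen after the data were seen. The others were fixed before the data were examined. Of the 426 higher and 292 lower genes, total-count scaling gave 1182 and 123, as it moved the median of all genes by 0.42 in log2. Totals without the 20 most abundant genes moved it by 0.12 and gave 559 and 218. Without a filter the counts were 1287 and 1063 of 16643 genes, and at a mean CPM of at least 10 they were 153 and 125 of 5380. A threshold of 1.5-fold gave 1169 and 1087, and 3-fold gave 170 and 97. Without the loci of shared count differences there were 384 and 264, and after removal of the length and GC trend 411 and 240. The other settings gave counts within 1.5 times, from 407 to 426 higher and 290 to 305 lower. Among them, division by RefSeq transcripts changed only the intervals, not the ratios. Counts were also 426 and 292 without an interval criterion, so this setting does not test how reads summed over transcripts affect the ratios. The log2 ratio of Rora was −0.050 with total-count scaling and −0.35 without the 20 most abundant genes, against −0.47 to −0.48 elsewhere.

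List medians were compared relative to the median of all measured genes, so a scaling leaves their percentiles as they are. By the mean of members the PPARγ list stood at 1.48 and the fatty acid oxidation list at 1.34, as a mean gives more weight to members with large ratios. The fatty acid synthesis list stayed between 0.63 and 0.76. The number of lists outside the central 95%, 18 as reported, ran from 15 to 21. Under the settings that changed list membership, values, filters, the random lists or the list statistic, 15 calls on 8 lists moved across that limit. Of these, 5 were for pericentral genes and 2 each for stellate, housekeeping and hepatocyte genes, and the cause was not tested. Of 148 named genes, 11 changed sign with total-count scaling, which moves all genes alike. Leaving out a replicate, a paired fit and other splits of the samples need more than 1 library per group and were not run. No paired analysis was possible because each genotype has 1 library. Depth limits genes with few counts, such as Cyp2b13 and Hsd3b4, and the spread between animals was not measured.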

Other observations

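The carboxylesterase 1 genes, a cluster on chromosome 8 whose products hydrolyse lipid esters and drugs, were mostly higher in the library labelled LKO. Ces1e was 16.2-fold (interval 15.8 to 16.5) higher, Ces1g 8.91-fold, Ces1f 6.78-fold and Ces1d 4.44-fold. Ces1c was 1.34-fold higher, and Ces1b had a log2 ratio of −0.41, which turns positive with total-count scaling. Ces1a, at 80 and 45 counts, lay under the limit for measured genes. As these genes are close copies, the split between them is uncertain. Apart from Ces1d, Ces1g and Lipe, the genes of this and the next paragraph were chosen after their values were seen, as were Xist, the Y-linked and growth hormone genes and Mir1983 below.

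Several regulators and secreted factors also differed. Txnip, which encodes a thioredoxin-binding protein induced by glucose, was 4.79-fold (interval 4.68 to 4.91) higher, and Gdf15, a stress-induced hormone gene, 4.86-fold higher. The hormone-sensitive lipase gene Lipe was 2.24-fold higher and the liver transcription factor gene Foxa2 2.05-fold higher. Nnmt, which methylates nicotinamide, was 9.41-fold (interval 8.65 to 10.3) lower.

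Of the tests below, only the 3 that remove a trend with length and GC content were set before the result they measure was seen. The others were chosen afterwards, and the rules for the growth hormone genes and for the genes ranked by ratio were made stricter after their values were known. All patterns rest on 1 library per genotype, so a difference between individual animals, litters or handling cannot be told apart from genotype.

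Male-biased genes were lower and female-biased genes higher in the library labelled LKO. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty argue against a female source. Their summed CPM ratio was 1.07, library labelled LKO over control. Xist, expressed from the inactive X, had 0 and 36 counts, the latter 0.236 CPM, so a small female share in the library labelled LKO stays open. A small share could lower male-biased genes only by about its own size. Of these genes 23 of 24 were at least 1.5-fold lower, with a median of −2.01, which argues against such a share as their source. Its part in the female-biased ratios was not tested. Reads shared between Mup copies do not account for the male-biased pattern either, as the 16 male-biased genes other than Mup had a median of −2.01. After removal of the length and GC trend the male-biased median was −1.75 and the female-biased median 1.24, both beyond all random lists. Medians over length deciles ran only from −0.28 to 0.14. The trend was thus too small for its removal to bring medians of −2.01 and 1.06 inside the random range. A candidate explanation is a difference in growth hormone and STAT5 signalling, which sets this sex bias, but 6 genes of that pathway had a median of 1.17 with 3 above 0 and 3 below, and with total-count scaling the median was 1.59 with 5 above 0, so this stays open. Cish, Socs2 and Onecut1 were 11.1-fold, 7.02-fold and 5.60-fold higher, and Igf1 was 1.48-fold lower, while Bcl6, a male-biased repressor outside these 6, was 5.16-fold lower.

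Genes with short transcripts were lower as groups. Of 77 measured cytosolic ribosomal protein genes, 68 were at least 1.5-fold lower and 0 higher, and their median longest transcript was 1094 nt, against 1735 nt for respiratory chain genes and 3322 nt for all measured genes. Removing the length and GC trend moved the ribosomal protein median from −0.81 to −0.63 and the respiratory chain median from −0.42 to −0.24. Both stayed below the central 95% of random lists, which began at −0.10 and −0.17, so the trend as fitted did not remove the difference. Length was that of the longest annotated transcript, which need not be the one expressed, and the fit left these genes out. How much of the difference length accounts for therefore stays open. The respiratory chain median is about 0 with total-count scaling, and whether genotype contributes was not tested.

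Many of the most extreme ratios lay at loci with repeated gene copies. Of the 20 genes ranked by ratio, 11 had another gene within 250 kb whose count difference was within 5% of theirs or a whole multiple, against 8.21% of 402 other 2-fold genes, counting differences of at least 500. At the Zfp184 locus, Pom121l2, Zfp184 and Prss16 had exactly 3, 6 and 12 times the 747 counts of Mir1983 in the control library, and all were at 0 in the library labelled LKO. A candidate explanation is alignments that span neighbouring copies and are counted in the genes between them, but it was drawn from these same counts, so the comparison of shares restates what was seen and the explanation stays open. The other 9 of the 20 had no such neighbour, which leaves their source untested. They were Cyp2b9, Rgs16, Duxbl1, Cyp4a31, Hsd3b4, Hsd3b5, Serpina3j, Tff3 and Hist1h4n, several of them from families of close copies.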
